A study of Homo sapiens with 7 samples.

How the data were processed

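RNA was measured in 7 libraries of an established human prostate cancer line and its xenografts: 1 library of cultured 22Rv1-Luc2 cells, 3 of 22Rv1 tumors and 3 of 22Rv1-M4 tumors. Per the labels, the tumors were flash frozen and the libraries were stranded mRNA libraries. The deposited values are FPKM per locus as scaled by the authors; per the submitters' processing notes they were made with TopHat2 2.0.13 and Cufflinks, with the builds hg19 and mm10 named and no role given for either. Loci carry hg19 chromosome names. How mouse reads were treated, the kind of scaling between libraries and the strand of counting are not stated. All 7 columns could be assigned to a sample.

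Of 28963 loci, 4963 have no gene name, 813 are named for several genes and 1179 lie off the primary chromosomes. Loci were matched to symbols by name; the UGT1A genes share 1 locus, and values of closely related genes (KLK2 and KLK3, the UGT2B, metallothionein, alpha-globin and ribosomal protein genes with their pseudogenes) depend on how shared reads were assigned. Total reads are unknown, so no counting interval or detection floor is given. A depth relative to the cell-line library was read from the ratios between libraries of values under 0.3 FPKM, where 54.5 to 60.7% of value pairs per tumor lay within 0.04 log2 units of a simple ratio of whole reads. These depths are therefore approximate.

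Values were taken as log2(FPKM + 1). Fold changes on this scale understate differences in genes near or below 1 FPKM, so group means in FPKM are given beside them. The tumor groups were compared in the 6 tumor libraries over loci with at least 1 FPKM in at least 3 libraries. Each tumor group was compared with the cells in a model of 3 groups and 7 libraries, over loci with at least 1 FPKM in at least 1 library. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all loci tested and a threshold of 0.05. The cell line has 1 library, so its spread was assumed to equal that of the tumors.

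The 39 gene lists include prostate lineages, cell cycle, metabolism, stress and immune responses, matrix, developmental genes, RNA quality and host cell types. They hold 897 genes, of which 845 have their own locus, 36 lie in a merged locus and 16 have none. Lists with at least 5 tested members were compared with all other loci by camera with a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison. Camera with an estimated correlation, fry, and counts adjusted over the list alone were computed beside it. For 6 host lists the mean log2(FPKM + 1) per library was compared between the tumor groups by a two-sided exact permutation test, whose smallest p is 0.1.

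Named genes in the comparison of tumor groups are the 12 with the highest and the 12 with the lowest log2 fold change among those past the threshold, with a mean of at least 2 FPKM in the higher group and no overlap between groups. Loci without a gene name, LOC, LINC, MIR and SNOR symbols and uncharacterised open reading frames are counted but not named. For each comparison with the cells they are the 8 highest and 8 lowest by the same rule. KLK3, KLK2, TMPRSS2, FOXA1, HOXB13, MEIS1 and MEIS2 are always given for the tumor groups, with up to 4 members past the threshold per list. The comparisons, lists, tests, naming rule and most alternatives were chosen before the data were examined; median ratio rescaling and quantile normalization of the list tests were added afterwards. Some genes and 1 list that these rules cover are counted in the totals and not described here.

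The fit was tested on simulated data with the same design, normal noise and the fitted spread, which the cell-line library shared with the tumors. Changed genes were drawn at a mean log2(FPKM + 1) of at least 2, so recovery at lower levels was not tested. Of 100 genes changed 2-fold, 99 were called between tumor groups, 73 between 22Rv1 tumors and cells and 67 between 22Rv1-M4 tumors and cells. Of a further 100 genes changed 4-fold, 100, 98 and 99 were called. Unchanged genes made up 3.40%, 5.0% and 7.26% of the calls with the 4-fold genes included. Of 30 simulated lists, the list with shifted genes was called each time and 0 of the unshifted lists were. Genes were simulated independently of each other, so this does not check the preset correlation.

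Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 FPKM, median ratio rescaling, quantile normalization, no trend, a robust trend, array weights, each library left out in turn, a 2-fold minimum, a block for replicate number, a fit with all 7 libraries, all 6 tumors as one group, and host list genes left out. Chromosomal position was examined by shuffling the order of loci and with Fisher's exact test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these tests and the figures. Splice variants and reads were not analysed here, and Y-linked loci were left out of the chromosome counts.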

Results

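RNA was sequenced from a xenograft model of human prostate cancer: 1 library of cultured 22Rv1-Luc2 cells, 3 libraries of tumors grown from 22Rv1 cells and 3 of tumors grown from 22Rv1-M4 cells. 22Rv1 is an established human prostate carcinoma line, and Luc2 is a firefly luciferase reporter used for imaging. The labels name 22Rv1-M4 without saying how it was derived, and the series title calls the set an in vivo progression model. Expression is given as fragments per kilobase of transcript, scaled to the library (FPKM), for 28963 loci on hg19, of which 4963 carry no gene name. At least 1 FPKM was reached by 12887 loci in the cells, by 14060, 13429 and 13348 loci in 22Rv1 tumors 1 to 3, and by 13292, 12999 and 13551 loci in 22Rv1-M4 tumors 1 to 3. Total read numbers are unknown, so no counting interval is given. Ratios between the lowest values give an approximate depth relative to the cell-line library of 0.752, 0.763 and 0.533 for the 22Rv1 tumors and of 0.799, 0.622 and 0.735 for the 22Rv1-M4 tumors. Unnamed loci took 33.4% of summed FPKM in the cells and up to 83.6% in 22Rv1 tumor 3. FPKM is given per kilobase, so short loci weigh more in this sum than their reads. The sum is therefore not a share of reads. Across loci, Pearson's r between libraries was 0.986 to 0.990 within the 22Rv1 tumors, 0.988 to 0.990 within the 22Rv1-M4 tumors, 0.974 to 0.978 between the tumor groups and 0.954 to 0.969 between tumors and cells; loci are not independent replicates. The first principal component held 40.2% of the variance and the second 29.5%.

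The comparison of 22Rv1-M4 with 22Rv1 tumors asks how tumors of these lines differ. LPIN2, a phosphatidate phosphatase of lipid synthesis on chromosome 18 (2916992 to 3014475), had the highest log2 fold change of the genes that the rule for names covers, 5.59 ± 0.13 (SE), and went from 2.10 ± 0.336 to 149 ± 17.1 FPKM (mean ± SD, n = 3 per group, here and below). SERPINE2, a secreted serine protease inhibitor on chromosome 2 (224839765 to 224904036), went from 12.3 ± 5.33 to 362 ± 47.6 FPKM, and the small leucine-rich proteoglycan lumican (LUM) from 3.86 ± 0.447 to 84.4 ± 8.41 FPKM. In the other direction, SLC7A5, the large neutral amino acid transporter, went from 179 ± 22.3 to 17.4 ± 2.77 FPKM and UGT2B4, a glucuronosyltransferase, from 24.2 ± 2.04 to 0.842 ± 0.391 FPKM. Adjusted p in limma was at most 4.01e-06 for LPIN2, LUM and UGT2B4, 5.73e-06 for SLC7A5 and 2.07e-05 for SERPINE2. The rule for names chose genes past the threshold without overlap between groups, so differences beyond the spread between replicates were part of the choice.

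Of 13569 loci tested with limma, 2367 passed an adjusted p of 0.05, 1017 higher and 1350 lower in 22Rv1-M4 tumors; 250 and 433 of them differed at least 2-fold, and 214 had no gene name. The groups of 3 did not overlap at 35.9% of tested loci, where chance gives 10%. The count depends on the libraries: it was 1169 without 22Rv1 tumor 1, 1411 without 22Rv1 tumor 2, 1431 without 22Rv1-M4 tumor 1 and 1357 without 22Rv1-M4 tumor 3. Without the filter on low values 2187 passed, and 1640 of the 2367 were among them.

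Besides LPIN2, SERPINE2 and LUM, the 12 increases named by the rule were in ADAM7 (log2 fold change 4.57, from 0.832 to 41.9 FPKM), the lectin LGALS4 (4.17, from 40.2 to 696), the fatty acid-binding protein FABP7 (5.50 to 91.0), angiotensinogen (AGT, 3.82, from 1.05 to 27.6), the proteoglycan SPOCK2 (3.74, from 7.12 to 107), SERPINA5 (3.61, from 0.0131 to 11.4), DAPL1 (3.52, from 2.62 to 39.4), IER5L (3.49, from 18.9 to 214) and SCARNA16. The SCARNA16 locus, which spans 75084725 to 75213183 on chromosome 17, far more than the small RNA it is named for, was listed at 0 in every 22Rv1 tumor and at 12.4 ± 5.41 FPKM in 22Rv1-M4 tumors. Among the 12 decreases named by it, the amino acid transporter SLC7A8 (log2 fold change -4.17) had 34.6 ± 36.0 FPKM in 22Rv1 tumors and 0.424 ± 0.0760 in 22Rv1-M4 tumors. BASP1 (-4.11, from 30.9 ± 24.9 to 0.108 ± 0.0549 FPKM) and CYP4F8 (-3.66, from 48.3 ± 30.8 to 2.24 ± 0.985) also varied widely between the 22Rv1 tumors, and the BASP1 call ended without the filter on low values (adjusted p = 0.0506) and with a robust variance trend (adjusted p = 0.108). The conjugating-enzyme loci that fell were UGT2B4 (-3.79), UGT2B11 (-3.40, from 27.0 to 1.66 FPKM) and the merged UGT1A locus (-3.58, from 16.2 to 0.458). HOPX fell by 3.40 on the log2 scale, SLC7A5 by 3.30 and CHRD, an extracellular antagonist of bone morphogenetic proteins, by 3.29. The neuropeptide genes NMB (-3.14, from 72.5 to 7.26 FPKM) and VGF (-3.12, from 27.5 to 2.26) were also in this set. SLC7A5 stood at 802 FPKM and VGF at 229 FPKM in the cultured cells.

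**Figure D1:**
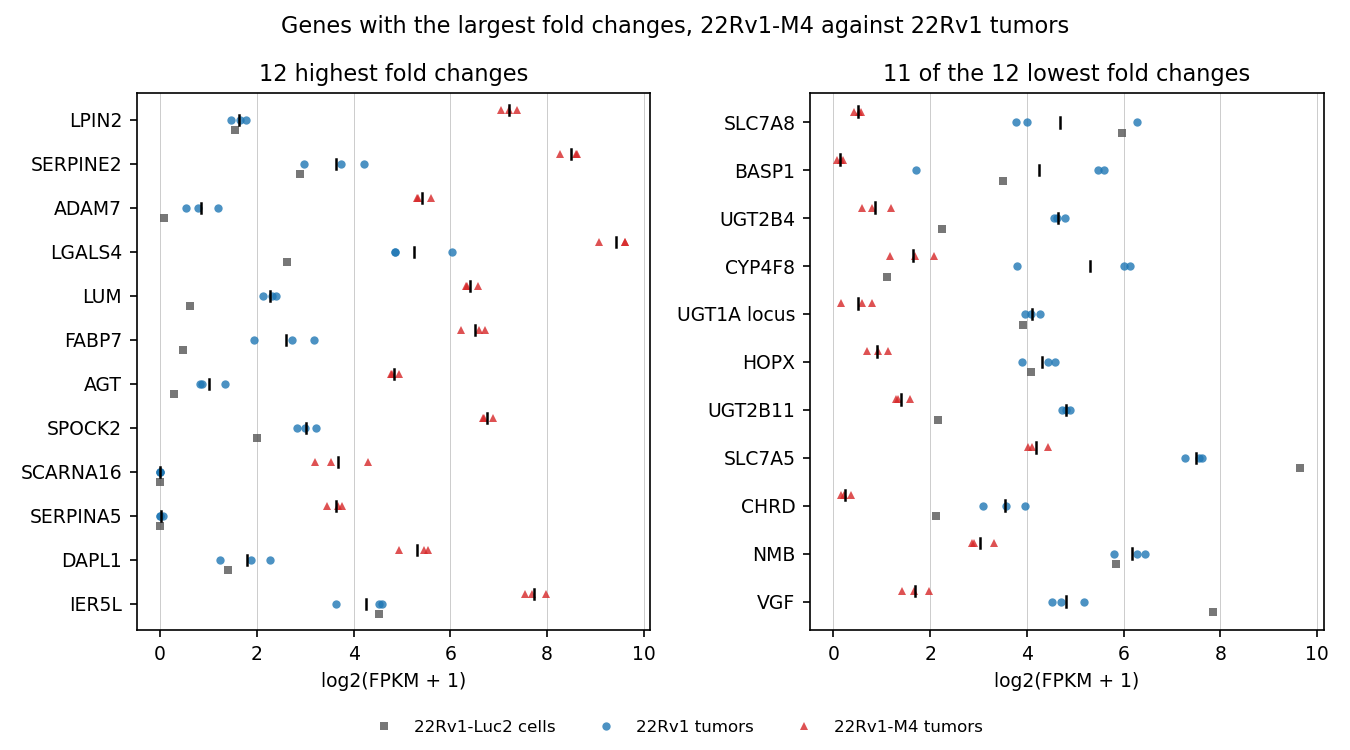
Expression of the 12 genes with the highest and 11 of the 12 with the lowest fold change between 22Rv1-M4 and 22Rv1 tumors under the rule for names. Each point is 1 library on the log2(FPKM + 1) axis, vertical bars mark the mean of 3 tumors, and the cell line has 1 library; a lack of overlap between the tumor groups was part of the choice of genes.

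Among genes of the prostate lineage, KLK3, which encodes prostate-specific antigen, fell by 1.63 on the log2 scale (16.2 ± 1.28 to 4.65 ± 1.37 FPKM, adjusted p = 0.000403) and TMPRSS2 by 1.39 (21.5 ± 3.55 to 7.63 ± 1.82, adjusted p = 0.00127). KLK2 (33.3 ± 5.84 and 28.7 ± 4.01 FPKM, adjusted p = 0.413), FOXA1 (115 ± 11.9 and 93.4 ± 2.48, 0.138) and HOXB13 (58.7 ± 18.0 and 71.7 ± 14.1, 0.385) did not pass. The homeobox cofactor genes MEIS1 (1.37 ± 0.761 and 0.837 ± 0.0138 FPKM) and MEIS2 (0.468 ± 0.342 and 0.134 ± 0.0673 FPKM) were too low to be tested.

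**Figure D2:**
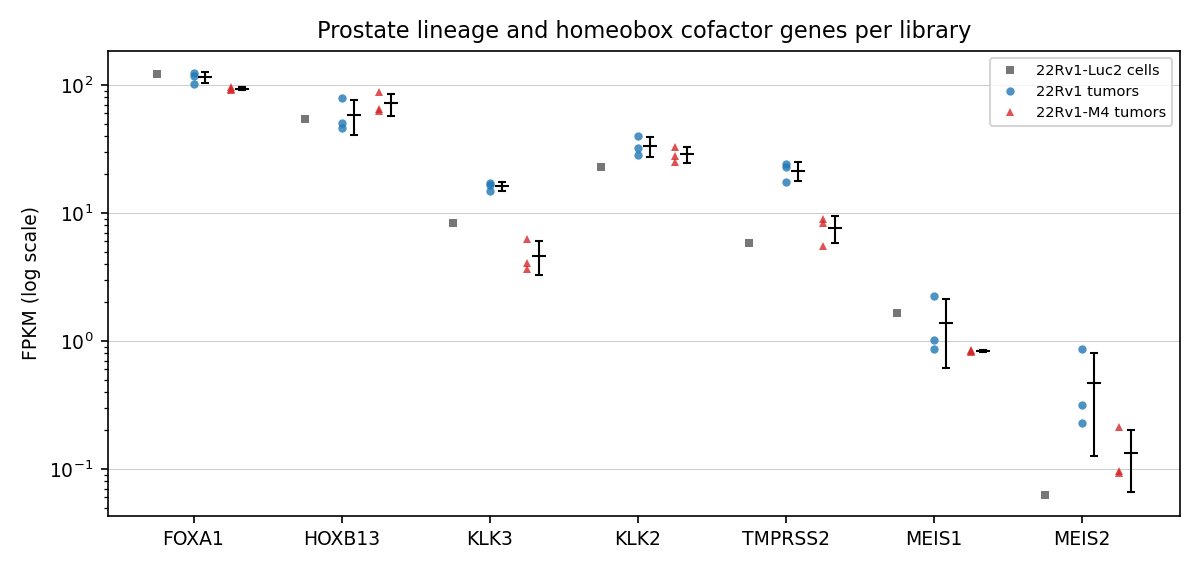
FPKM on a log axis of genes of the prostate lineage and homeobox cofactors in the cell-line library, 3 22Rv1 tumors and 3 22Rv1-M4 tumors. Points are libraries and black marks are the mean ± SD of 3 tumors, with KLK3 at 16.2 and 4.65 FPKM in the tumor groups.

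Of 31 gene lists with at least 5 tested members, 11 passed the camera test with a preset correlation, 5 of them higher and 6 lower in 22Rv1-M4 tumors, and 10 of the 11 are described here. None passed with a correlation estimated from the data, where 3 lists had an unadjusted p under 0.05, so that p is given beside each list described; 12 passed in fry, which tests whether a list's genes move one way on balance. Of the 11, hypoxia (fry adjusted p = 0.134) and G1/S (0.240) did not pass fry, whereas proteoglycans (0.00118), host fibroblasts (0.00654) and immediate early genes (0.0295), which camera did not call, did. The ribosomal protein list was fixed as a sign of RNA quality and is among the 11. Each list described here was thus compared between groups that also differed in this sign (median 0.64).

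The lists for ribosomal proteins, type I interferon response, antigen presentation, metallothioneins and G1/S were higher in 22Rv1-M4 tumors in camera with a preset correlation. Of 34 cytosolic ribosomal protein genes, 15 rose and 0 fell (29 and 0 adjusted over the list alone), with a median log2 fold change of 0.64 (camera adjusted p = 7.48e-15, and adjusted p = 0.580 with an estimated correlation). The median shrank to 0.16 when all libraries were given the same distribution of values by quantile normalization. RPS18 was 0.95 higher (adjusted p = 0.0381) and lost its call without 22Rv1 tumor 1 (0.152), 22Rv1 tumor 2 (0.0955), 22Rv1 tumor 3 (0.0869), 22Rv1-M4 tumor 1 (0.0680) or 22Rv1-M4 tumor 3 (0.103), and without the filter on low values (0.387). Type I interferon response genes rose at 9 of 23 members and fell at 1 (10 and 1 adjusted over the list alone). Their median was 0.34 on the log2 scale (camera adjusted p = 0.000187, and adjusted p = 0.320 with an estimated correlation). IFITM1, a membrane protein that restricts virus entry, went from 3.73 ± 1.45 to 23.1 ± 1.53 FPKM, IFI44L from 0.373 to 3.63 and MX1, a dynamin-like antiviral GTPase, from 0.753 to 3.46. Of 10 antigen presentation genes 5 rose and 1 fell (5 and 2 adjusted over the list alone). Their median was 0.37 on the log2 scale (camera adjusted p = 0.0395, and adjusted p = 0.580 with an estimated correlation). The immunoproteasome subunit genes PSMB8 (1.52 to 7.96 FPKM) and PSMB9 (0.343 to 3.04) and the peptide transporter gene TAP1 (4.90 to 9.99) were among them; the table lists PSMB8 and TAP1 over the same span, so the same reads could count for both. Beside these immune lists, the mean log2(FPKM + 1) of macrophage and leukocyte markers was 0.386 ± 0.0208 in 22Rv1 tumors and 0.439 ± 0.00400 in 22Rv1-M4 tumors (exact permutation p = 0.1, the smallest that 3 against 3 allows). LCP1, the single tested marker, rose from 10.5 ± 1.41 to 19.3 ± 1.49 FPKM with 13.8 in the cells. The summed FPKM of the 20 markers was 14.4 in 22Rv1 tumors and 23.3 in 22Rv1-M4 tumors, so most of this difference came from LCP1. Since the cultured cells also express LCP1, the list cannot tell host leukocytes from tumor cells here. Metallothionein genes, whose products bind zinc and copper, rose at 4 of 8 members and fell at 0 (4 and 1 adjusted over the list alone), as in MT1G (57.4 to 178 FPKM) and MT1X (183 to 361). Their median was 0.73 on the log2 scale (camera adjusted p = 0.0395, and adjusted p = 0.580 with an estimated correlation). Of 30 genes for G1/S transition and DNA replication 4 rose and 0 fell, with the same counts adjusted over the list alone. Their median was 0.18 on the log2 scale (camera adjusted p = 0.00438, and adjusted p = 0.648 with an estimated correlation). TYMS, which makes thymidylate, went from 44.9 to 66.0 FPKM, and its call ended without 22Rv1 tumor 1 (0.0780), 22Rv1 tumor 2 (0.0539) or 22Rv1-M4 tumor 1 (0.0715).

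The lists for fatty acid synthesis, the unfolded protein response and amino acid stress, hypoxia, TGF-beta and BMP targets and steroid metabolism were lower in camera with a preset correlation. Fatty acid synthesis genes fell at 9 of 17 members and rose at 1 (11 and 1 adjusted over the list alone). Their median was -0.57 on the log2 scale (camera adjusted p = 0.000187, and adjusted p = 0.580 with an estimated correlation). Fatty acid synthase (FASN) went from 422 ± 69.5 to 133 ± 9.22 FPKM, the acyl-CoA synthetase ACSL3 from 154 to 64.9 and the lipogenic transcription factor SREBF1 from 52.3 to 22.8. In the list for the unfolded protein response and amino acid stress, 9 of 27 genes fell and 0 rose (13 and 2 adjusted over the list alone). Their median was -0.34 on the log2 scale (camera adjusted p = 0.000360, and adjusted p = 0.629 with an estimated correlation). Members that fell include SLC7A5, the partner subunit SLC3A2 (174 to 75.8 FPKM) and the disulfide isomerase PDIA4 (178 to 80.5). Hypoxia genes fell at 11 of 28 members and rose at 1 (12 and 1 adjusted over the list alone). Their median was -0.45 on the log2 scale (camera adjusted p = 0.000360, and adjusted p = 0.648 with an estimated correlation). The glucose transporter SLC2A3 went from 11.5 ± 6.95 to 0.268 ± 0.0527 FPKM, carbonic anhydrase CA12 from 12.7 to 1.58, and the prolyl hydroxylase EGLN3 fell by 2.29 on the log2 scale. TGF-beta and BMP target genes fell at 7 of 15 members and rose at 0 (11 and 1 adjusted over the list alone), including the inhibitors of differentiation ID1 (40.7 to 15.3 FPKM), ID2 (49.6 to 16.2) and ID4 (7.91 to 1.41). Their median was -0.44 on the log2 scale (camera adjusted p = 0.000450, and adjusted p = 0.320 with an estimated correlation). Steroid metabolism genes fell at 5 of 14 members and rose at 1 (7 and 1 adjusted over the list alone). Their median was -0.37 on the log2 scale (camera adjusted p = 0.00951, and adjusted p = 0.334 with an estimated correlation). UGT2B11 and the steroid reductase SRD5A1 (19.8 to 12.2 FPKM) fell.

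**Figure D3:**
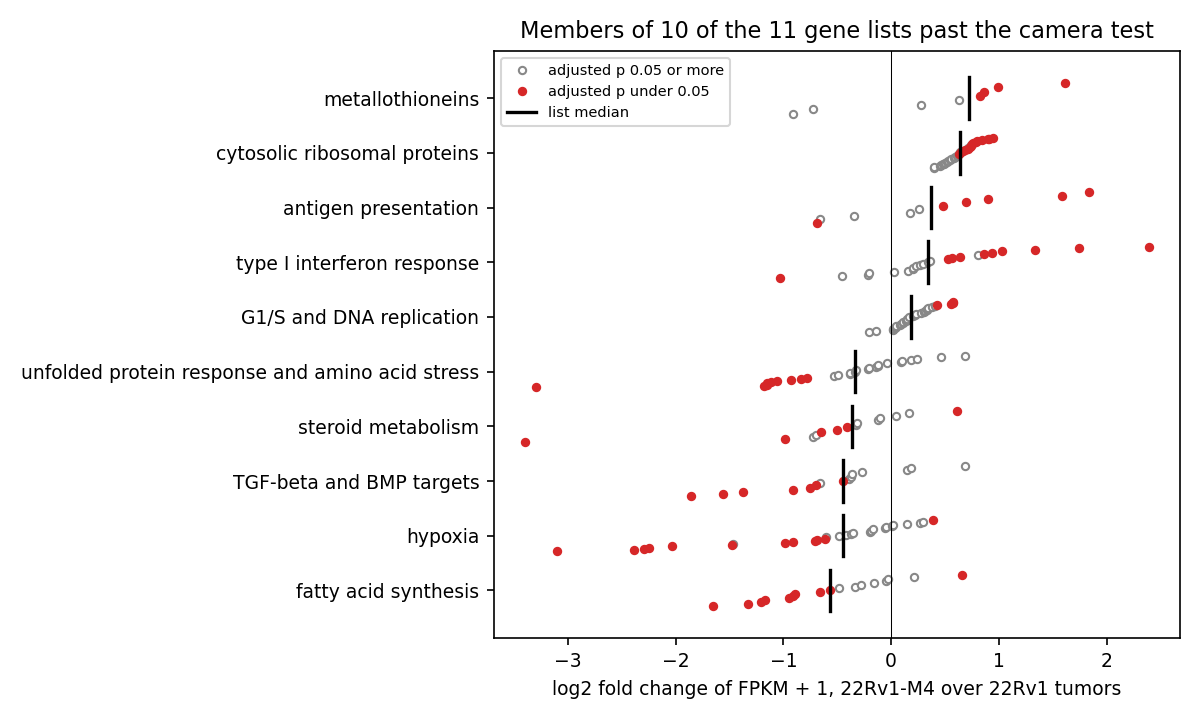
Log2 fold changes between 22Rv1-M4 and 22Rv1 tumors of the tested members of 10 of the 11 lists that passed the camera test with a preset correlation. Each point is 1 gene, filled where its own adjusted p was under 0.05, and black bars are list medians, from -0.57 for fatty acid synthesis to 0.73 for metallothioneins.

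Without 22Rv1-M4 tumor 2 only 7 lists passed: the calls that ended include antigen presentation (adjusted p = 0.147), metallothioneins (0.0835) and G1/S (0.0835). The call for antigen presentation also ended without 22Rv1 tumor 3 (0.0830), 22Rv1-M4 tumor 1 (0.0944) or 22Rv1-M4 tumor 3 (0.108) and with quantile normalization (0.0754), and that for metallothioneins without 22Rv1 tumor 1 (0.0523) or 22Rv1 tumor 3 (0.0754), with a pseudocount of 0.1 (0.0515) and with quantile normalization (0.0808). Other lists passed in fits without 1 library. Replication-dependent histone genes, fixed as a sign of RNA quality, did so without 22Rv1-M4 tumor 1 (adjusted p = 0.0140, median 0.66 against 0.15), and p53 targets without 22Rv1 tumor 3 (0.0434). Without 22Rv1 tumor 2 the G2/M (0.0255), oxidative phosphorylation (0.0261) and immediate early (0.0372) lists passed, and without 22Rv1-M4 tumor 3 MYC targets (0.0214) and G2/M (0.0378).

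With all 6 tumors the other 20 lists did not pass, although single members changed. Proteoglycan and heparan sulfate genes had 5 of 15 members higher and 1 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.157); decorin (DCN) went from 0.792 to 4.85 FPKM and syndecan SDC2 from 22.2 to 63.4, while fibromodulin (FMOD) went from 7.98 ± 5.82 to 0.117 ± 0.137. In the mesenchymal transition list 3 of 13 genes rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.928): fibronectin (FN1) went from 1.62 to 19.4 FPKM, while the collagen-crosslinking enzyme LOX went from 19.2 to 2.82 and CD44 from 19.5 to 4.70. Neuroendocrine genes fell at 4 of 7 members and rose at 0 (4 and 1 adjusted over the list alone; camera adjusted p = 0.176), as in SNAP25 (4.64 to 1.75 FPKM). Among 24 p53 target genes 4 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.144); the stress cytokine GDF15 went from 34.8 to 4.20 FPKM and the cell cycle inhibitor CDKN1A from 28.4 to 8.89. Immediate early genes, fixed as a sign of handling, fell at 4 of 19 members, including KLF4 (19.7 to 3.68 FPKM), and rose at 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0841).

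For the remaining lists the numbers of members that rose and fell were 3 and 0 of 28 for G2/M (0 and 0 adjusted over the list alone), 1 and 0 of 27 for MYC targets (0 and 0), 0 and 0 of 34 for oxidative phosphorylation (0 and 0), 1 and 2 of 19 for glycolysis (1 and 2), 0 and 3 of 25 for cholesterol synthesis (0 and 3) and 1 and 1 of 7 for inflammatory NF-kB genes (1 and 1). They were 1 and 2 of 16 for the luminal lineage (1 and 4), 1 and 2 of 22 for epithelial junctions (1 and 3), 0 and 2 of 13 for HOX and MEIS genes (1 and 4), 3 and 0 of 12 for matrix proteases and inhibitors (3 and 0) and 0 and 1 of 15 for heat shock (0 and 0). They were 2 and 1 of 8 for Wnt targets (2 and 1), 1 and 2 of 10 for cancer-testis antigens (1 and 2), 3 and 3 of 23 for replication-dependent histones (3 and 4) and 3 and 3 of 7 for host fibroblast markers (3 and 4). Camera adjusted p for these 15 lists was at least 0.0995. The sign of the median differed from that of the camera test in 3 lists, cholesterol synthesis (0.03, mean -0.07), host fibroblasts (-0.53, mean 0.28) and mesenchymal transition (0.05, mean -0.14), and the mean of the inflammatory NF-kB list (-0.04) differed in sign from its median (0.08) and test. Lists with under 5 tested members were the basal epithelium and mitochondrially encoded lists (0 each), macrophages (1, which rose), endothelium and bone (2 each, 1 of each rose), erythroid cells (2, both of which fell) and muscle and adipocytes and keratinocytes (2 each, 0 changed).

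Markers of mouse host cells were read through human loci. The mean log2(FPKM + 1) of 22 fibroblast markers was 0.459 in the cells, 0.748 ± 0.0680 in 22Rv1 tumors and 0.754 ± 0.0115 in 22Rv1-M4 tumors (exact permutation p = 1.0, two-sided). Erythroid markers had 0.524 ± 0.186 and 0.0492 ± 0.0409 (exact permutation p = 0.1), from alpha-globin loci that also stood at 4.48 and 4.51 FPKM in the cultured cells. Keratinocyte markers gave an exact permutation p of 0.1, endothelial markers 0.3 and muscle and adipocyte markers 1.0, and no adjusted value over the 6 lists was under 0.2. LUM and DCN, which rose, are markers of the fibroblast list, whereas COL5A1 of that list fell (2.88 to 0.155 FPKM).

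The comparison of 22Rv1 tumors with the cultured cells describes how 22Rv1 xenografts differ from luciferase-labelled 22Rv1 cells in culture. In camera with a preset correlation the hypoxia list was higher in the tumors and the lists for cholesterol synthesis and for G1/S and DNA replication were lower. With an estimated correlation adjusted p was 0.592 for each of the 3. None of them passed fry (adjusted p = 0.0630, 0.101 and 0.106). NDRG1, a hypoxia-responsive gene, stood at 12.1 FPKM in the cells and 228 ± 40.2 FPKM in the tumors (log2 fold change 4.11, adjusted p = 0.00022), and the neuropeptide NPY at 0.349 and 24.4 ± 7.12 (4.20, adjusted p = 0.000385). IGFBP3, a secreted binding protein for insulin-like growth factors, stood at 175 FPKM in the cells and 7.55 ± 3.27 in the tumors (-4.44, adjusted p = 0.000984). There was 1 cell-line library, so its spread was assumed to equal that of the tumors and no replicate checks it.

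Among 16234 tested loci, 2316 passed in limma, 1308 higher and 1008 lower in 22Rv1 tumors, and 1161 passed without 22Rv1 tumor 1. The balance turned without the filter on low values (922 higher and 1070 lower) and with quantile normalization (1174 and 1232). The other increases named by the rule were in TM4SF1 (0.203 to 25.5 FPKM), PEBP4 (1.24 to 45.3), S100P (21.6 to 434), CYP4F8 (1.16 to 48.3), the METTL12 and SNORA57 locus (3.51 to 84.2) and CLPSL1, listed at 0 in the cells and at 29.6 ± 10.4 FPKM in the tumors. The CYP4F8 call ended without the filter (adjusted p = 0.0541) and with a robust variance trend (0.0750). The decreases named besides IGFBP3 were in TEX15 (44.8 to 1.13 FPKM), the protease PRSS23 (56.1 to 2.74), CPLX2 (23.5 to 0.982), the transcription factor GATA3 (log2 fold change -3.55), the cytokine signaling suppressor SOCS1 (14.0 to 0.545), N-cadherin (CDH2, 17.1 to 0.894) and CA12 (128 to 12.7).

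Camera with a preset correlation passed 17 of 32 lists, 8 higher and 9 lower, not all of which are described; with an estimated correlation 0 passed and 2 had an unadjusted p under 0.05. Fry passed 5 of the 17, among them host fibroblasts (adjusted p = 0.0192), neuroendocrine genes (0.0192), immediate early genes (0.0325) and Wnt targets (0.0454). Hypoxia genes rose at 19 of 28 members and fell at 1 (24 and 1 adjusted over the list alone). Their median was 1.24 on the log2 scale (camera adjusted p = 2.67e-09, and adjusted p = 0.592 with an estimated correlation). SLC2A3 was listed at 0 in the cells and at 11.5 ± 6.95 FPKM in the tumors, whereas CA12 fell. Host fibroblast markers rose at 5 of 9 members and fell at 0 (6 and 0 adjusted over the list alone), among them LUM and COL1A1 (1.42 to 4.08 FPKM). Their median was 0.95 on the log2 scale (camera adjusted p = 0.0106, and adjusted p = 0.591 with an estimated correlation). Ribosomal protein genes, fixed as a sign of RNA quality, had 0 of 34 members past the threshold in either direction, also adjusted over the list alone, at a median of 0.43 (camera adjusted p = 0.000129, and adjusted p = 0.688 with an estimated correlation). This call ended with quantile normalization, at a median of 0.00 (adjusted p = 0.820).

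Cholesterol synthesis genes fell at 6 of 25 members and rose at 0 (13 and 0 adjusted over the list alone): HMGCS1 went from 196 to 63.1 FPKM. Their median was -0.67 on the log2 scale (camera adjusted p = 3.68e-06, and adjusted p = 0.592 with an estimated correlation). Genes of G1/S and DNA replication fell at 8 of 30 members and rose at 0 (13 and 1 adjusted over the list alone), as in RRM2 (log2 fold change -1.08). Their median was -0.47 on the log2 scale (camera adjusted p = 1.46e-05, and adjusted p = 0.592 with an estimated correlation). G2/M genes fell at 3 of 28 members and rose at 0 (8 and 0 adjusted over the list alone), including BUB1 (25.4 to 14.4 FPKM). Their median was -0.24 on the log2 scale (camera adjusted p = 0.00117, and adjusted p = 0.592 with an estimated correlation). Neuroendocrine genes fell at 4 of 11 members and rose at 0 (5 and 1 adjusted over the list alone), as in SNAP25 (19.2 to 4.64 FPKM). Their median was -0.42 on the log2 scale (camera adjusted p = 0.0117, and adjusted p = 0.591 with an estimated correlation). Wnt targets fell at 5 of 17 members and rose at 0 (6 and 1 adjusted over the list alone), RNF43 among them (9.51 to 3.78 FPKM). Their median was -0.49 on the log2 scale (camera adjusted p = 0.0117, and adjusted p = 0.592 with an estimated correlation).

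A further 8 lists passed, and each of these calls ended in at least 1 fit without 1 library. Immediate early genes (5 rose and 2 fell of 19, 7 and 2 adjusted over the list alone, median 0.39), such as NR4A1, had a camera adjusted p of 0.0416, 0.592 with an estimated correlation and 0.0596 without 22Rv1 tumor 3. Glycolysis (5 and 2 of 19, 9 and 2 adjusted over the list alone, median 0.37) had 0.0416, 0.592 with an estimated correlation, 0.0529 without 22Rv1 tumor 1, 0.0600 without 22Rv1-M4 tumor 2 and 0.119 with quantile normalization. The luminal lineage (6 and 0 of 18, 7 and 1 adjusted over the list alone, median 0.46), which includes KRT18 (263 to 633 FPKM), had 0.0472, 0.592 with an estimated correlation, 0.0564 without 22Rv1 tumor 2, 0.131 without 22Rv1 tumor 3, 0.0509 without 22Rv1-M4 tumor 1 and 0.0600 without 22Rv1-M4 tumor 2. Metallothioneins (2 and 0 of 9, also adjusted over the list alone, median 0.61) had 0.0492, 0.592 with an estimated correlation, 0.0679 without 22Rv1 tumor 2, 0.0770 without 22Rv1 tumor 3, 0.0812 without 22Rv1-M4 tumor 2 and 0.0548 with median ratio rescaling. Amino acid stress genes (0 and 7 of 27, 0 and 8 adjusted over the list alone, median -0.23), among them SLC7A5, had 0.0117, 0.688 with an estimated correlation and 0.0699 without 22Rv1 tumor 3. MYC targets (0 and 1 of 27, 0 and 0 adjusted over the list alone, median -0.23) had 0.0312, 0.662 with an estimated correlation, 0.0529 without 22Rv1 tumor 1 and 0.0640 with quantile normalization. Oxidative phosphorylation (0 and 1 of 34, 0 and 0 adjusted over the list alone, median -0.16) had 0.0416, 0.794 with an estimated correlation, 0.149 without 22Rv1 tumor 1 and 0.110 without 22Rv1 tumor 3. Bone-associated genes (0 and 3 of 7, 1 and 3 adjusted over the list alone, median -0.56) had 0.0472, 0.592 with an estimated correlation, 0.0509 without 22Rv1-M4 tumor 1, 0.0600 without 22Rv1-M4 tumor 2 and 0.0640 with quantile normalization.

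Fatty acid synthesis did not pass against the cells (4 rose and 3 fell of 17; 4 and 6 adjusted over the list alone; camera adjusted p = 0.737), and its median (-0.17) differed in sign from its mean (0.13). The camera test differed in sign from the median for TGF-beta and BMP targets (median 0.10, mean -0.22), p53 targets (median 0.02, mean 0.02) and histones (median 0.20, mean 0.15), and from the mean for proteoglycans (median -0.21, mean 0.15) and interferon genes (median -0.08, mean 0.02). The remaining lists had a camera adjusted p of at least 0.1, and none of them passed with all libraries; HOX and MEIS genes passed without 22Rv1 tumor 3 (0.0192).

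The comparison of 22Rv1-M4 tumors with the cultured cells shares its single cell-line library with the previous one, so the overlap of both is not read as a shared effect. LGALS4 stood at 5.13 FPKM in the cells and 696 ± 139 FPKM in 22Rv1-M4 tumors (log2 fold change 6.81, adjusted p = 0.000139), and the related lectin LGALS2 at 0.577 and 117 ± 32.1 (6.18, adjusted p = 2.92e-05). NPY stood at 0.349 and 92.1 ± 16.3 FPKM and the glutathione transferase GSTA1 at 0.517 and 87.5 ± 11.6. IGFBP3 fell to 0.276 ± 0.178 FPKM (-7.12, adjusted p = 6.1e-05), VGF to 2.26 ± 0.630 (-6.16, adjusted p = 2.34e-05) and SLC7A5 from 802 to 17.4 ± 2.77 FPKM (-5.46, adjusted p = 8.05e-06).

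In limma 3360 of 16234 loci passed, 1645 higher and 1715 lower, and 2000 passed without 22Rv1-M4 tumor 3; array weights gave 5155. The balance turned with a pseudocount of 0.1 (2042 higher and 1682 lower) or 0.5 (1786 and 1710), with median ratio rescaling (1795 and 1561), with no trend (1675 and 1633) and without 22Rv1-M4 tumor 1 (1178 and 1157), so neither direction is read as the larger. FABP7 (0.383 to 91.0 FPKM), LUM (0.536 to 84.4), LPIN2 (1.91 to 149) and SERPINE2 (6.43 to 362) complete the 8 named increases. CRIP1 (78.1 to 0.552 FPKM), CA12 (128 to 1.58), SLC7A8 (61.4 to 0.424), TEX15 (44.8 to 0.460) and APLP1 (32.0 to 0.267) complete the 8 named decreases.

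With a preset correlation 14 of 32 lists passed camera, 5 higher and 9 lower, not all of which are described; with an estimated correlation 0 passed and 3 had an unadjusted p under 0.05. Fry passed 12. Of the 14 it did not pass cholesterol synthesis (adjusted p = 0.0571), fatty acid synthesis (0.0571), heat shock (0.133), hypoxia (0.159) and G1/S (0.230). It passed host fibroblasts (0.00146), TGF-beta and BMP targets (0.00206) and proteoglycans (0.00813), which camera did not. Ribosomal protein genes, fixed as a sign of RNA quality, rose at 22 of 34 members and fell at 0 (31 and 0 adjusted over the list alone). Their median was 1.05 on the log2 scale (camera adjusted p = 2.69e-14, and adjusted p = 0.542 with an estimated correlation), and 0.09 with quantile normalization. Hypoxia genes rose at 10 of 28 members and fell at 1 (12 and 2 adjusted over the list alone). Their median was 0.75 on the log2 scale (camera adjusted p = 0.000882, and adjusted p = 0.617 with an estimated correlation). Metallothioneins rose at 4 of 9 members and fell at 0, also adjusted over the list alone, as in MT1X (42.1 to 361 FPKM). Their median was 0.91 on the log2 scale (camera adjusted p = 0.00919, and adjusted p = 0.542 with an estimated correlation). Interferon response genes rose at 6 of 25 members and fell at 1 (7 and 1 adjusted over the list alone), among them IFI44L (0.137 to 3.63 FPKM). Their median was 0.40 on the log2 scale (camera adjusted p = 0.0195, and adjusted p = 0.509 with an estimated correlation). The mean log2(FPKM + 1) of macrophage and leukocyte markers was 0.331 in the cells and 0.439 ± 0.00400 in these tumors.

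Cholesterol synthesis genes were lower at 10 of 25 members and higher at 0 (14 and 0 adjusted over the list alone), as in LSS (48.5 to 18.9 FPKM). Their median was -0.69 on the log2 scale (camera adjusted p = 6.12e-06, and adjusted p = 0.604 with an estimated correlation). The amino acid stress list had 12 of 27 genes lower and 0 higher (16 and 0 adjusted over the list alone): asparagine synthetase (ASNS) went from 134 to 32.5 FPKM and PHGDH, of serine synthesis, from 125 to 41.5. Their median was -0.69 on the log2 scale (camera adjusted p = 1.49e-05, and adjusted p = 0.565 with an estimated correlation). Wnt targets fell at 8 of 17 members and rose at 1, also adjusted over the list alone, as in DKK1 (5.43 to 0.142 FPKM). Their median was -0.55 on the log2 scale (camera adjusted p = 0.00148, and adjusted p = 0.514 with an estimated correlation). Neuroendocrine genes fell at 6 of 11 members and rose at 2 (8 and 2 adjusted over the list alone), as in the synaptic vesicle gene SYP (41.6 to 4.19 FPKM). Their median was -1.13 on the log2 scale (camera adjusted p = 0.00319, and adjusted p = 0.509 with an estimated correlation). Steroid metabolism genes fell at 6 of 15 members and rose at 1, also adjusted over the list alone, UGT2B15 among them (72.7 to 11.3 FPKM). Their median was -0.33 on the log2 scale (camera adjusted p = 0.0131, and adjusted p = 0.509 with an estimated correlation). Fatty acid synthesis genes fell at 9 of 17 members and rose at 3 (11 and 3 adjusted over the list alone), as in the desaturase SCD (323 to 75.9 FPKM). Their median was -0.58 on the log2 scale (camera adjusted p = 0.0182, and adjusted p = 0.604 with an estimated correlation). Heat shock genes fell at 4 of 17 members and rose at 0, also adjusted over the list alone. Their median was -0.47 on the log2 scale (camera adjusted p = 0.0182, and adjusted p = 0.604 with an estimated correlation). Bone-associated genes fell at 2 of 7 members and rose at 0 (4 and 0 adjusted over the list alone), including PTHLH (3.73 to 0.533 FPKM). Their median was -0.73 on the log2 scale (camera adjusted p = 0.0193, and adjusted p = 0.509 with an estimated correlation). Genes of G1/S and DNA replication fell at 4 of 30 members and rose at 1, also adjusted over the list alone, a call that ended without 22Rv1-M4 tumor 1 (0.0521) or 22Rv1-M4 tumor 3 (0.0894). Their median was -0.29 on the log2 scale (camera adjusted p = 0.0225, and adjusted p = 0.697 with an estimated correlation). Median and mean differed in sign for mesenchymal transition (-0.10 and 0.14), inflammatory NF-kB genes (0.11 and -0.03) and cancer-testis antigens (-0.12 and 0.01), none of which passed. Oxidative phosphorylation, not called with all libraries, passed without 22Rv1-M4 tumor 2 (adjusted p = 0.0326) and with quantile normalization (0.0412).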

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

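In this part the depth and host tests of the unnamed loci were chosen before their results were seen, although the loci themselves were noticed in the data. The range required of the host means was not part of the rule fixed beforehand. Against the cultured cells, 22 loci were past the threshold in opposite directions in the tumor groups, with the difference between the tumor groups itself past it in limma. UGT2B4 stood at 3.78 FPKM in the cells, 24.2 ± 2.04 in 22Rv1 tumors and 0.842 ± 0.391 in 22Rv1-M4 tumors (log2 fold change between tumor groups -3.79). UGT2B11 stood at 3.46, 27.0 ± 1.76 and 1.66 ± 0.285 FPKM (-3.40), and CHRD at 3.37 FPKM in the cells and 0.186 ± 0.0859 in 22Rv1-M4 tumors (-3.29). The growth factor gene TGFB3 moved the same way (15.0, 39.4 ± 5.35 and 3.89 ± 1.12 FPKM), whereas ASPH moved the other way (35.1, 18.6 ± 0.934 and 104 ± 7.71 FPKM); both were named after their values were seen. All of these rest on 1 cell-line library.

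Among loci without a gene name, 5 spans of 103 to 125 bases were listed at 0 in the cells and at 100 FPKM or more in all 6 tumors, while 0 named loci met the same rule. The locus with the highest values, on chromosome 10 (116450045 to 116450147), ranged from 8501 to 230107 FPKM. At such short lengths few reads can give a high FPKM. Too few reads in the cell-line library cannot be told apart from a true absence, although all 6 tumor libraries were shallower by the approximate depths: if the library with the fewest reads held 1, the shallowest tumor library, 22Rv1 tumor 3, would hold a median of 23.2 reads, but it is also the highest for 4 of the 5 loci. The same assumption gives minima for the cells. At the tumors' median level they would be expected to hold at least 19.8 reads over the 5 loci, which goes against low depth. At the tumors' lowest level a median of 1.61 per locus would be expected, but the assumed 1 read and the relative depths alone fix this value, so it decides nothing. The loci were also chosen for being at 0 in the cells. RNA of mouse host cells also stays open. Spearman's rho between these loci and the mean of the fibroblast, endothelial and macrophage lists over the tumors was -0.49 (exact permutation p = 0.356). Pearson's r was -0.73 (exact permutation p = 0.151), and -0.01 without the 2 farthest tumors. By the rule fixed beforehand a rho under 0 counts against host RNA. The host means, however, spanned only 0.0410 log2 units, under the required range of 0.1, so no conclusion is drawn from rho. The highest levels in any tumor were 94.1 FPKM for LUM, 20.5 for LCP1 and 3.55 for ENG, 5 fibroblast, 2 macrophage and 3 endothelial markers also reached 1 FPKM in the cultured cells, and no biological explanation was tested.

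For the 2367 loci past the threshold between the tumor groups, 10 splits of 6 tumors into 3 and 3 are too few for a share under 0.05; as many loci came from 1 split, the real one, and the highest count among the others was 2.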

How the results depend on the processing

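The rescalings of the list tests were chosen after the data were seen. Between the tumor groups the count of 2367 stayed within 1.5 times under each pseudocount, without a filter, under both rescalings, under no or a robust trend, array weights, all 7 libraries and without host list genes, but only 1640 of the 2367 kept their call without a filter. It was 1479 with a filter of 5 FPKM, which tests fewer loci, and 683 with a 2-fold minimum. Without 1 library it ranged from 1169 (without 22Rv1 tumor 1) to 2215 (without 22Rv1-M4 tumor 2). The filter still required 1 FPKM in 3 libraries, so some called loci were no longer tested. Of the 2367, 2094 or 2095 were tested without a 22Rv1 tumor and 2235 or 2236 without a 22Rv1-M4 tumor. Causes beyond this and the smaller number of libraries were not tested. A block for replicate number gave 2064, with 1935 of the 2367 kept. Without 1 library the 22Rv1 tumors against cells gave 1161 (without 22Rv1 tumor 1) to 2549, and the 22Rv1-M4 tumors against cells 2000 (without 22Rv1-M4 tumor 3) to 3594. Array weights gave 3460 and 5155, and all 6 tumors as one group against cells 2947; the cause was not tested. Loci higher in 22Rv1 tumors than in cells were the smaller part without a filter (46.3%) and with quantile normalization (48.8%). With quantile normalization 7 of the 3360 loci called between 22Rv1-M4 tumors and cells turned direction. No list passed with an estimated correlation (0, 0 and 0 of 31, 32 and 32 lists in camera); without 1 library 7 (without 22Rv1-M4 tumor 2) to 14 lists passed between tumor groups, and 13 to 17 and 13 to 15 against the cells. Of the called named genes, 51 of 123 between tumor groups, 69 of 113 for 22Rv1 tumors and 82 of 120 for 22Rv1-M4 tumors against cells were tested and called in every setting (78, 72 and 99 in each setting that tested them). Of the 133 genes followed between tumor groups, 3 uncalled host markers turned direction: CFD (-0.000359 and -3.42e-05 with pseudocounts of 0.1 and 0.5, -0.0065 with median ratio rescaling, -0.14 with array weights, -0.22 to 0.14 without 1 library), FLG (0.0865 with quantile normalization, 0.16 with array weights, -0.0552 to 0.21 without 1 library) and MB (-0.0151 with array weights, -0.10 to 0.10 without 1 library). HBA2 in 22Rv1 tumors against cells ranged from -0.77 to 0.26 without 1 library. Unknown depth limits what can be said of genes near 0.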

Other observations

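Of the tests in this part, that of the ribosomal protein genes with closely matched genes was chosen after the result was seen, as was setting aside the match of the whole list for its difference in level. The test of the members without close matches covers the genes that this later match left over. The balance of loci that rose and fell differed between chromosomes. On chromosome 8, 69 of 461 loci were higher in 22Rv1-M4 tumors and 31 lower (median log2 fold change 0.13; Fisher's exact test, adjusted p = 1.91e-06 over 23 chromosomes). Chromosome 6 also leaned higher (72 and 58 of 676, adjusted p = 0.0282), and chromosomes 16 (29 and 69 of 620, 0.0380) and 22 (17 and 50 of 364, 0.0282) leaned lower. Fisher's test takes loci as independent, whereas all calls came from the same 6 tumors and neighbouring loci changed together, as given below. The p values for chromosomes may therefore be too small. Windows of 20 loci passed the 95% limits of shuffled order on chromosome 8 from 22022408 to 25273233, with 9 higher and 0 lower of 20 loci, among them ADAM7 and STC1, with an overlapping window from 22409251 to 26230195 (8 and 0 of 20), and on chromosome 6 from 44355251 to 52860742 (7 and 0 of 20). The windows that passed in the other direction lay on chromosome 2 from 127928830 to 136634011 (0 higher and 13 lower of 32) and on chromosome 4 from 57204252 to 71853891 (2 and 7 of 25), where HOPX, UGT2B4, UGT2B11 and UGT2B15 lie. Windows were judged by their mean log2 fold change, which a few large changes can move. On chromosome 4 the mean reached -0.80 (limit -0.68), but the median of the region was -0.06. Medians were 0.26 and 0.22 on chromosome 8, 0.41 on chromosome 6 and -0.35 on chromosome 2. The means on chromosome 8, 0.608 and 0.5977, lay close to the limit of 0.5976.

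Neighbouring loci changed in the same direction in 415 adjacent pairs, against a median of 183 and a highest of 229 in 10000 shuffled orders. Reads shared by overlapping loci or by neighbours with like symbols are argued against as the whole cause. Leaving out overlapping loci kept 332 of these pairs and, with 29 between new neighbours, gave 361 (95th percentile 199). Without pairs whose symbols share their first 4 characters, 402 were kept (95th percentile 200). Pairs of unnamed loci stayed in this last count. Neither count can detect a transcript split over adjacent loci that do not overlap, so that stays open. No biological explanation was tested.

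Ribosomal protein genes were higher in 22Rv1-M4 tumors by a median of 0.64 on the log2 scale. A single unusual 22Rv1-M4 library is argued against as the whole cause. The lowest median without 1 of the 22Rv1-M4 tumors was 0.495, without tumor 2. The list median over the 22Rv1 tumor mean was 0.917 in 22Rv1-M4 tumor 2, 0.469 in tumor 1 and 0.4995 in tumor 3. In the 22Rv1 tumors it ranged from -0.121 to 0.0526. Part of the size of the difference therefore rests on 22Rv1-M4 tumor 2. A bias by length or level is argued against as the whole cause for the 16 members with close matches: other genes within 0.5 log2 units of level and 2-fold of length had a median of 0.14 against 0.65. The upper limit of 10000 matched draws, 0.304, lay just under the 0.323 that the test required. The draws measure the choice of matched genes and not the spread between tumors. For the other 18 such a bias cannot be told apart, since only 7 other named genes reach their levels, with a median of 0.37 against 0.63. Matching of the whole list (0.11) decides nothing because the matched genes lay lower (median level 9.55 against 11.53 log2 units). Quantile normalization gives every library one distribution and would also lessen a true shift of genes that hold the top ranks, as many of these do. The median of 0.16 with it therefore decides nothing, and the size of this difference stays open.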
